A study of Mus musculus with 50 samples.

How the data were processed

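RNA was taken from the left ventricle of 50 mice of the C57BL/6J background, aged 40 weeks. The mice carried a transgene that overexpresses LARP6 in cardiomyocytes (Tg) or were wild-type littermates (WT). Each received sterile saline or angiotensin II (Ang II, a peptide hormone that raises blood pressure) at 1000 ng per kg of body weight per minute, and tissue was collected after 21 days. Per the labels, poly(A) RNA was selected and made into libraries by a dUTP method, which keeps the strand of the RNA, and sequenced as paired ends. Each library was taken as a different animal, since every library number occurs once; no numbers pair the libraries.

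The authors list cutadapt 1.9, FastQC, HISAT2 2.0.4 and StringTie 1.3.4d as their tools. The deposited table held, for each gene and library, a count and an FPKM value (fragments scaled to transcript length and to the mapped fragments of the library). The authors' counts were whole numbers and were used as deposited. The authors' FPKM values are already divided by gene length and by library size, so they carry no information on depth of their own. Neither the counting tool, the strand setting of the counting nor the genome build was stated. Of the 35717 genes in the table, 35599 were found by identifier in GENCODE M21, which is built on mouse assembly GRCm38. Of these, 91.6% had identical start and end positions there and 99.9% lay within 100 kb at both ends, so positions are given on that assembly. The table held 0 genes with a count of 0 in every library, and 74 gene symbols belonged to more than 1 gene. The transgene's promoter and sequence were not described, so fragments from the transgene and from the mouse's own Larp6 gene were counted together.

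Groups were taken from the sample labels. They are 5 WT saline females, 6 WT saline males, 7 WT Ang II females, 7 WT Ang II males, 6 Tg saline females, 6 Tg saline males, 7 Tg Ang II females and 6 Tg Ang II males. For 2 libraries the letters of the table's column name gave another genotype than the label. These are library 329 (replicate 5 of the WT Ang II males, with Tg letters) and library 847 (replicate 6 of the Tg Ang II males, with WT letters). Both were joined to their labels by number and kept under the labelled genotype. Each main count is also given without both, an alternative chosen after seeing the data, but the counts taken in each sex alone are not.

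The tests, gene lists, thresholds and the rule for naming genes were fixed before the data were examined. That plan assumed a table of FPKM alone, with limma-trend as the test, and named the quasi-likelihood test of edgeR in case counts were present. As the table held counts, edgeR was used, and limma-trend became an alternative. Genes with an FPKM of at least 1 in at least 5 libraries were tested, 11628 in all, and these held between 98.9% and 99.3% of each library's counts. Counts were scaled by the median-of-ratios method, which sets a typical gene to be unchanged between libraries. The quasi-likelihood model had 1 mean for each of the 8 groups, and females and males were weighted equally in every comparison that joins them. P values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested. A gene was called at an adjusted p under 0.05. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of data.table. Larp6 was also tested by a two-sided permutation test with 1e+05 resamples of the genotype labels on log2(scaled FPKM + 1).

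Differences are log2 fold changes ± standard error (SE) from edgeR. Levels are the authors' FPKM values divided by a median-of-ratios factor per library, 0.775 to 1.13 over the 50 libraries, and are given as mean ± SD. They cover 11 WT saline, 14 WT Ang II, 12 Tg saline and 13 Tg Ang II libraries, or n = 25 per genotype and per sex. Total counts per library ranged from 53877400 to 91579300. The median gene tested had a mean count of 1198 per library, for which counting error alone gives a coefficient of variation of 2.89%, and the lowest 10% of genes had at most 195 (7.16% or more). The lowest chi-square per gene between 2 libraries of a group was 21.5, so no 2 libraries of the same group were alike within counting error.

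Genes named in every comparison were Larp6, Nppa, Nppb, Myh7, Acta1, Col1a1, Col1a2, Col3a1, Postn and Ccn2. Each comparison added the called genes with the largest rises and falls, up to 10 in each direction, among genes with a mean scaled FPKM of at least 5 in a group compared. Each list added up to 4 tested members with the smallest p. Sardh and the members Dkk3 and Stard10 of a list of 3 genes were named after their values were seen.

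The 37 gene lists covered the following. For the heart muscle cell, they held hypertrophy and load markers, ventricular sarcomere and identity genes, calcium handling and ion channels, and atrial markers. For the matrix, they held the collagen mRNAs known as LARP6 partners, all collagens, other matrix genes, collagen processing, myofibroblast markers, TGF-beta signalling and resident fibroblast markers. For metabolism, they held nuclear-encoded respiratory chain subunits, mitochondrially encoded protein genes, fatty acid use, glucose use, the renin-angiotensin and natriuretic system, endoplasmic reticulum stress, immediate early genes, the cell cycle, antioxidant NRF2 targets, the circadian clock, the La-related protein family and sex-chromosome genes. For other cells, they held interferon response, inflammation, macrophage, MHC class II, T cell, B and plasma cell, endothelial, large-vessel endothelial, mural (pericyte and smooth muscle), adipocyte, brown adipocyte, erythroid, mesothelial, and nerve and Schwann cell genes. Lists with at least 3 tested members, 31 of the 37, were tested with camera in limma on log2 CPM (counts scaled to library size) with a prior count of 2. Camera compares a list with all other genes at a preset correlation of 0.01 between members. It was repeated with the correlation estimated from the libraries, and beside it fry tested whether a list's genes moved, on balance, one way. Adjusted p values of lists are over the 31 lists of a comparison. Some lists share genes, so their results are not independent. Postn, Comp, Ccn2, Cilp, Thbs1 and Ltbp2 are in both the myofibroblast and the other matrix list. Ccn2 and Ltbp2 are also TGF-beta genes. Of the resident fibroblast markers, Lum, Dcn and Mfap5 are also other matrix genes and Col6a3 is also a collagen. List members called were counted over all genes tested and adjusted over the list alone. Enrichment of GO and KEGG terms of 10 to 500 tested genes was tested by a one-sided Fisher's exact test against the 11628 genes, adjusted over the terms.

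Alternatives chosen in advance were limma-trend on log2(scaled FPKM + 0.1), no filter beyond an FPKM above 0, an FPKM of at least 5, no scaling beyond library size, quantile normalization and quality weights in voom, a robust fit, only the groups of a comparison, an additive sex term, a 1.5-fold minimum, leaving out each library in turn, and a block for clusters of library numbers. Library numbers more than 20 apart started a new cluster, which gave 10 clusters. No batch or date was labelled, so these clusters stand in for cohorts without being known to be such. Alternatives chosen after seeing the data were DESeq2, TMM scaling, limma-trend on log2(scaled FPKM + 1), voom with median-of-ratios scaling, and leaving out libraries 329 and 847, these with library 965, or these with the number block, leaving out library 965 alone for the gene lists, and leaving out libraries 965 and 715 for Ang II in each sex of Tg. The method was also tested on simulated counts, drawn anew with each gene's mean and fitted spread and each library's size. They copied neither the clusters of library numbers nor single libraries that stand apart. Known changes were placed on some genes. At 1.5-fold, 85.1% of such genes were recovered for Ang II in WT, 86.6% for Ang II in Tg, 74.6% for the difference between these responses and 25.4% for the 3-way difference with sex.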

Results

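Gene expression was measured by RNA sequencing in the left ventricle of 50 mice, 25 transgenic for LARP6 in cardiomyocytes (Tg) and 25 wild-type littermates (WT). LARP6 is an RNA-binding protein known to bind the 5′ stem-loop of the mRNAs of type I and type III collagen, the main fibres of scar tissue. Mice received saline or Ang II for 21 days, which gave 11 WT saline, 14 WT Ang II, 12 Tg saline and 13 Tg Ang II hearts with both sexes in each. The series asks how cardiomyocyte LARP6 bears on the loss of heart function and the fibrosis that follow Ang II. Total counts per library ranged from 53877400 to 91579300. Between 9832 and 11109 genes per library had an FPKM of at least 1. Transcripts of the mitochondrial genome took 28.1% to 38.8% of counts, and the 5 most abundant genes took 19.5% to 27.6%.

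Larp6 (ENSMUSG00000034839, chromosome 9, 60712989 to 60738801 on the plus strand, GRCm38) was far higher in Tg than in WT hearts. Its mean level was 33.4 ± 17.4 scaled FPKM in WT saline (SD, n = 11), 106 ± 256 in WT Ang II (n = 14), 1010 ± 298 in Tg saline (n = 12) and 954 ± 184 in Tg Ang II (n = 13). The log2 fold change between the genotypes was 4.27 ± 0.32 (SE, adjusted p = 4.0e-15). It was 4.78 without library 329, which is labelled WT. Larp6 in WT libraries other than 329 stood at 3.39% of the Tg mean in CPM. Reads carried between libraries may account for part of that share, so the fold change may be a lower limit. On log2(scaled FPKM + 1) the means were 9.89 in Tg and 5.26 in WT (n = 25 each), and a two-sided permutation test gave p = 1e-05, the smallest these permutations can give. All 25 Tg libraries, the lowest at 444, lay above every WT library other than 329, the highest of which was at 63.4. Library 329, replicate 5 of the WT Ang II males, stood at 995, within the Tg range, and made most of the WT Ang II mean. Without libraries 329 and 847, WT Ang II hearts had 38.1 ± 12.9 scaled FPKM. In the first principal component of all genes tested, which held 24.1% of the variance, library 329 lay at 16.5, where Tg libraries began at 3.68 and the other WT libraries ended at 8.24.

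**Figure D1:**
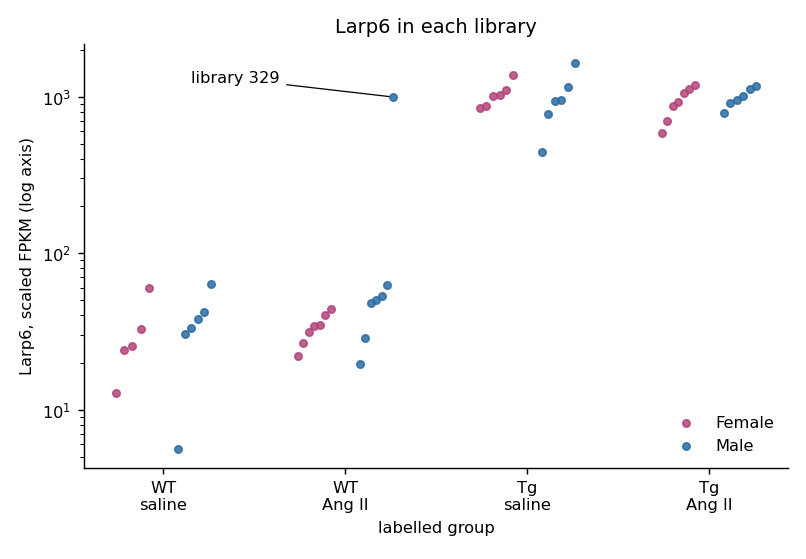
Larp6 level of each library in scaled FPKM (log axis), by labelled genotype and treatment, coloured by sex. The library labelled WT at 995 is library 329, and the other WT libraries end at 63.4 while Tg libraries start at 444.

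Under saline, the transgene went with higher load markers and matrix genes and lower genes of fatty acid use, which addresses what LARP6 does without Ang II. Nppa, the atrial natriuretic peptide that adult ventricles make under load, rose from 132 ± 38.7 to 1139 ± 511 scaled FPKM (log2 fold change 3.07 ± 0.28 SE, adjusted p = 1.4e-11). Myh7, the slow myosin heavy chain of the fetal and stressed mouse ventricle, rose from 153 ± 25.9 to 653 ± 172 (2.06 ± 0.23, adjusted p = 1.4e-09). Ankrd1, a stretch-responsive titin-associated repressor, rose by 2.38 ± 0.22, Nppb by 1.75 ± 0.31 and Ccn2, a secreted growth factor of connective tissue, by 2.16 ± 0.20. Acta1, skeletal actin, did not pass the test (118 ± 61.5 and 121 ± 42.2, 0.12 ± 0.23, adjusted p = 0.72). The other largest rises were Rprm, a cell-cycle arrest gene (4.86 ± 0.41, with WT libraries other than 329 at 3.83% of the Tg mean), Sprr1a (4.07 ± 0.43), Nmrk2, a kinase of NAD synthesis (2.44 ± 0.29), Cilp (2.35 ± 0.31), Lgals3 (2.31 ± 0.27) and Ccn5 (2.12 ± 0.30). The share of Rprm in WT may also hold carried reads, so the fold change of Rprm may be a lower limit.

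The largest falls under saline were in Scn4b, a subunit of the cardiac sodium channel (10.8 ± 2.22 to 2.30 ± 1.01 scaled FPKM, -2.32 ± 0.21, adjusted p = 9.5e-12), and Strit1, which encodes a peptide activator of the calcium pump (-1.69 ± 0.32). Lgals4 (-1.60 ± 0.19), Pfkfb1 (-1.50 ± 0.19), Mylk4 (-1.44 ± 0.17), Plxnb1 (-1.43 ± 0.15) and Ces1d, a lipid hydrolase (-1.37 ± 0.23), followed. Rpl3l, the striated-muscle form of a ribosomal protein (-1.40 ± 0.14), Amy1 (-1.24 ± 0.14) and Mir208b (-1.35 ± 0.14) also fell. Mir208b lies within Myh7, which rose, and the strand setting of the counting was not stated.

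Collagen and matrix genes were higher in Tg hearts under saline. The 3 collagen mRNAs known as LARP6 partners all rose, Col1a1 from 7.53 ± 1.65 to 13.9 ± 3.61 (0.88 ± 0.18), Col1a2 by 0.82 ± 0.15 and Col3a1 by 0.92 ± 0.25 (list adjusted p = 0.018, and adjusted p = 0.32 with an estimated correlation). Of 18 collagens, 13 rose and 0 fell, or 14 and 0 adjusted over the list alone (adjusted p = 8.3e-06, and adjusted p = 0.36 with an estimated correlation). Of 33 other matrix genes, 28 rose and 0 fell, or 28 and 2 adjusted over the list alone (adjusted p = 1.4e-13, and adjusted p = 0.14 with an estimated correlation). Postn, a matrix protein of activated fibroblasts, rose by 1.72 ± 0.26, and of 10 myofibroblast markers 8 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 1.6e-06, and adjusted p = 0.11 with an estimated correlation). Several of these markers, such as Postn, Ccn2 and Cilp, are also in the list of other matrix genes, so these lists are not separate results. Of 18 TGF-beta genes 10 rose, among them Tgfb2 (1.56), and 2 fell (adjusted p = 4.3e-04, and adjusted p = 0.11 with an estimated correlation). Of 17 collagen-processing genes 7 rose and 2 fell, and the list was not called.

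Markers of other cell types moved apart under saline. All 12 resident fibroblast markers rose, with a median log2 fold change of 0.49, among them Pi16 (1.25 ± 0.12) and Dpt (0.63), with a list adjusted p of 8.4e-07 and adjusted p = 0.11 with an estimated correlation. Of 15 macrophage markers 13 rose, with a median of 0.80, among them Lyz2, lysozyme (51.7 to 109 scaled FPKM), and C1qb (0.89), with an adjusted p of 2.4e-06 and adjusted p = 0.18 with an estimated correlation. Of 6 MHC class II genes 5 rose, H2-Eb1 by 0.53 (adjusted p = 0.031, and adjusted p = 0.45 with an estimated correlation). Of 13 endothelial markers 11 fell and 0 rose, with a median of -0.41, among them Tie1 (17.3 to 12.1 scaled FPKM) and Cdh5 (-0.50), with an adjusted p of 9.6e-07 and adjusted p = 0.14 with an estimated correlation. Of 6 large-vessel endothelial markers 5 fell, among them Sox17 (-0.66), with an adjusted p of 0.0030 and adjusted p = 0.14 with an estimated correlation. Of 11 mural markers 8 fell, such as Abcc9 (-0.93), while Acta2, smooth muscle actin, and Cspg4 rose by 1.22 ± 0.16 and 0.42 (adjusted p = 0.018, and adjusted p = 0.40 with an estimated correlation).

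Of the 11 hypertrophy and load markers 9 rose under saline and 0 fell, with a median of 1.33 (adjusted p = 9.8e-09, and adjusted p = 0.11 with an estimated correlation). Of 31 genes of fatty acid use 25 fell and 0 rose, with a median of -0.43, among them Ech1 of peroxisomal and mitochondrial oxidation (427 to 246 scaled FPKM) and Lpl (-0.47), with an adjusted p of 5.9e-14 and adjusted p = 0.14 with an estimated correlation. Of 69 nuclear-encoded respiratory chain subunits 21 fell and 4 rose, with a median of -0.06, of 0.07 without scaling beyond library size and of -0.16 without library 965, replicate 6 of the Tg saline males (adjusted p = 0.0014, and adjusted p = 0.70 with an estimated correlation). Of 13 mitochondrially encoded protein genes 11 fell with a median of -0.26, or -0.13 without scaling beyond library size (adjusted p = 2.2e-04, and adjusted p = 0.36 with an estimated correlation). Quantile normalization put that median at 0, with mt-Co3 turning to 0.01. That method sets the most abundant genes of every library to the same values, so it cannot tell whether genes as abundant as these fell. Of 25 calcium-handling and ion-channel genes 9 fell, among them Atp2a2, the calcium pump of the sarcoplasmic reticulum (-0.64 ± 0.07), and Hcn4 (-0.97), and 1 rose. The median of -0.12 was 0.02 without scaling beyond library size, with an adjusted p of 0.018 and adjusted p = 0.41 with an estimated correlation. Of 15 NRF2 targets 8 rose, among them Srxn1 (0.58) (adjusted p = 0.0086, and adjusted p = 0.31 with an estimated correlation). Of 3 atrial markers 2 rose (adjusted p = 0.021, and adjusted p = 0.11 with an estimated correlation). Ckm, muscle creatine kinase, fell from 500 to 294 scaled FPKM in a sarcomere and identity list of 16 genes, of which 5 fell and 3 rose and which was not called.

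In all, 4720 genes were called between the genotypes under saline, 2376 higher and 2344 lower in Tg, and 786 of them differed at least 1.5-fold (516 higher, 270 lower). Without libraries 329 and 847 the count was 4736, of which 4688 were shared. The GO term collagen-containing extracellular matrix held 102 of the genes that rose (of 179 tested, 36.6 by chance, adjusted p = 9.0e-24). The term mitochondrial matrix held 94 that fell (38.9 by chance, adjusted p = 9.8e-16), and KEGG branched-chain amino acid degradation held 31 of 43 (8.67 by chance, adjusted p = 4.0e-11). Without scaling beyond library size the median of all genes was 0.14 higher in Tg, 4868 genes were called higher and 919 lower, and the calls of the LARP6-partner collagens, MHC class II and atrial lists ended. With a block for library-number clusters 3970 genes were called and the MHC class II call ended.

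In WT hearts, Ang II raised load markers and matrix genes and lowered genes of fatty acid use. Nppa rose from 132 ± 38.7 to 537 ± 357 scaled FPKM (log2 fold change 2.05 ± 0.27 SE, adjusted p = 5.2e-07), and Acta1 rose from 118 ± 61.5 to 365 ± 207 (1.74 ± 0.24, adjusted p = 1.2e-06). Col1a1 rose from 7.53 ± 1.65 to 14.3 ± 6.06 (0.94 ± 0.18, adjusted p = 1.8e-04), and Postn from 3.52 ± 0.876 to 12.2 ± 8.57 (1.83 ± 0.26, adjusted p = 2.2e-06). The largest rises also held Cilp, a cartilage matrix protein made by cardiac fibroblasts (2.48 ± 0.30), Thbs4, a matricellular protein (2.19 ± 0.33), and the microfibril genes Mfap4 (1.92 ± 0.22) and Mfap5 (1.33 ± 0.18). Mt2, a metallothionein (1.38 ± 0.24), and Ankrd1 (1.28 ± 0.20) were among them as well, and Nppb rose by 1.06 ± 0.30, Ccn2 by 1.04 ± 0.19 and Myh7 by 0.83 ± 0.22 (0.54 ± 0.17 without libraries 329 and 847). Larp6 rose by 1.23 ± 0.40 (adjusted p = 0.024), a call that ended without library 329, and stood at 0.21 ± 0.23 (adjusted p = 0.58) without libraries 329 and 847.

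The largest falls in WT were in Efemp1, an elastic-fibre protein (4.49 ± 1.76 to 2.00 ± 0.801 scaled FPKM, -1.08 ± 0.14), Ces1d (39.8 ± 8.51 to 20.1 ± 9.01, -0.99 ± 0.22), Pfkfb1 (-0.95 ± 0.18) and Scn4b (-0.83 ± 0.19). Lgals4 (-0.75 ± 0.18), Plxnb1 (-0.73 ± 0.14), Dnaaf3 (-0.64 ± 0.11), Ppp1r3b (-0.63 ± 0.15), G0s2 (-0.63 ± 0.14) and Fbp2 (-0.63 ± 0.11) completed the set.

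All 11 hypertrophy and load markers rose in WT, with a median of 0.86 (list adjusted p = 1.2e-11, and adjusted p = 0.10 with an estimated correlation). The 3 LARP6-partner collagens rose, Col1a2 by 0.72 ± 0.15 and Col3a1 by 0.90 ± 0.24 (adjusted p = 0.0026, and adjusted p = 0.24 with an estimated correlation). Of 18 collagens 10 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 1.1e-06, and adjusted p = 0.42 with an estimated correlation). Of 33 other matrix genes 20 rose and 1, Thbs2, fell (26 and 1 adjusted over the list alone, adjusted p = 9.1e-13, and adjusted p = 0.24 with an estimated correlation). Of 10 myofibroblast markers 7 rose with a median of 1.09 (adjusted p = 1.2e-06, and adjusted p = 0.16 with an estimated correlation). Of 18 TGF-beta genes 8 rose, among them Ltbp2 (2.38), and 2 fell (adjusted p = 0.0055, and adjusted p = 0.24 with an estimated correlation). Of 17 collagen-processing genes 6 rose, such as P4ha1 (0.34), and 1 fell (adjusted p = 0.018, and adjusted p = 0.48 with an estimated correlation). Of 3 atrial markers 2 rose (adjusted p = 0.018, and adjusted p = 0.14 with an estimated correlation).

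Of 31 genes of fatty acid use 17 fell in WT and 0 rose (19 and 0 adjusted over the list alone), with Ech1 going from 427 to 305 scaled FPKM (-0.49 ± 0.09) and Acaa2 falling by 0.43 (adjusted p = 5.5e-08, and adjusted p = 0.42 with an estimated correlation). Of 17 interferon-stimulated genes 6 rose, among them Irf7 (0.64), Oas1a (0.55) and Ifit1 (0.50) (adjusted p = 0.0018, and adjusted p = 0.50 with an estimated correlation). Of 11 mural markers 4 fell, among them Notch3 (-0.48) and Smtn (-0.28) (adjusted p = 0.0027, and adjusted p = 0.42 with an estimated correlation). Of 13 mitochondrially encoded protein genes 3 fell, or 10 adjusted over the list alone, with mt-Nd1 at -0.23 and at -0.05 under quantile normalization (adjusted p = 0.0010, and adjusted p = 0.50 with an estimated correlation). Resident fibroblast markers, of which 2 of 12 rose and 1 fell, and macrophage markers, of which 3 of 15 rose and 1 fell, were not called as lists, nor were endothelial markers, of which 1 of 13 fell.

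Ang II changed 2160 genes in WT, 1129 higher and 1031 lower, of which 269 changed at least 1.5-fold (188 higher, 81 lower). The count was 1766 without libraries 329 and 847, of which 1727 were shared. The GO term collagen-containing extracellular matrix held 50 of the genes that rose (17.4 by chance, adjusted p = 7.2e-09) and Z disc held 35 (11.3 by chance). Mitochondrial matrix held 45 that fell (17.1 by chance, adjusted p = 1.6e-06). Without scaling beyond library size, 1987 genes were called higher and 477 lower, and the block for library-number clusters gave 2008.

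In Tg hearts, Ang II again raised Acta1, from 121 ± 42.2 to 373 ± 182 scaled FPKM (log2 fold change 1.64 ± 0.23 SE, adjusted p = 1.7e-05), and Xirp2, an actin-binding protein of the intercalated disc, from 32.2 ± 4.23 to 55.5 ± 14.5 (0.79 ± 0.10, adjusted p = 2.8e-06). Postn rose by 1.22 ± 0.25, Thbs4 by 1.25 ± 0.30, Cilp by 1.13 ± 0.28, Col8a1 by 0.80 ± 0.18 and Col1a1 by 0.56 ± 0.17 (13.9 ± 3.61 to 20.4 ± 5.99, adjusted p = 0.032). Mfap5 (0.79 ± 0.17), Uck2 (0.78 ± 0.14), Edn3, an endothelin (0.69 ± 0.15), and Fgl2 (0.67 ± 0.15) were the other largest rises. Csrp3 (0.27, adjusted p = 0.0069), Fhl1 (0.33, adjusted p = 0.0095) and Uchl1 (0.55, adjusted p = 0.033), load markers that were higher in Tg under saline, rose further. Of others that were higher under saline, Nppa (1139 ± 511 and 1603 ± 638, 0.51 ± 0.25, adjusted p = 0.20), Nppb (0.26 ± 0.29, adjusted p = 0.65), Ankrd1 (0.22, adjusted p = 0.54) and Ccn2 (0.41 ± 0.18, adjusted p = 0.15) did not pass the test. Myh7, at 653 ± 172 and 651 ± 225, gave -0.01 ± 0.21 (adjusted p = 0.98), a sign that other settings turn. Col1a2 (0.40 ± 0.14, adjusted p = 0.070) and Col3a1 (0.60 ± 0.23, adjusted p = 0.099) did not pass either.

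The largest falls in Tg were in Inmt, a methyltransferase (7.20 ± 2.81 to 2.71 ± 1.49 scaled FPKM, -1.41 ± 0.30), Ces1d (-0.92 ± 0.22), Pla2g5, a secreted phospholipase (-0.79 ± 0.10), and Clec3b (-0.76 ± 0.12). Cxcl14 (-0.64 ± 0.15), Gstt1 (-0.62 ± 0.12), Dpep1 (-0.59 ± 0.12) and the imprinted RNA H19 (-0.56 ± 0.15) followed. Rn7s1 (-1.09 ± 0.34) and Atp5k (-0.58 ± 0.17) were called with library 965, replicate 6 of the Tg saline males, and not without it (adjusted p = 0.32 for Rn7s1 and 0.13 for Atp5k).

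Of the 11 hypertrophy and load markers 5 rose in Tg and 0 fell, or 6 and 0 adjusted over the list alone (list adjusted p = 1.9e-06). The adjusted p of every list called in Tg was 0.62 with an estimated correlation. Of 18 collagens 6 rose and 0 fell, or 11 and 0 adjusted over the list alone (adjusted p = 4.2e-06), and of the 3 LARP6-partner collagens 1 rose, or 3 adjusted over the list alone (adjusted p = 0.015). Of 33 other matrix genes 8 rose, among them Sparc (0.62), and 3 fell, among them Thbs2 (-0.69) and Fbln1 (-0.46) (18 and 3 adjusted over the list alone, adjusted p = 1.4e-04). Of 10 myofibroblast markers 4 rose (adjusted p = 0.0011), and of 17 collagen-processing genes 0 were called, or 5 rose adjusted over the list alone (adjusted p = 0.017). Of 12 resident fibroblast markers 6 fell, among them Gsn, gelsolin (373 to 266 scaled FPKM, -0.52 ± 0.08), and Dpt (39.4 to 28.9), while Mfap5 rose (adjusted p = 0.0074). Of 19 genes of glucose use 5 rose, such as Pfkp (0.62) and Pgk1 (0.24), and 2 fell (adjusted p = 0.033).

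Camera also placed respiratory chain subunits lower with Ang II in Tg (3 of 69 fell, median -0.12, adjusted p = 3.5e-06), and macrophage markers (0 of 15 called, median -0.22, adjusted p = 0.0074). The same held for MHC class II genes (0 of 6 called, 5 lower adjusted over the list alone, median -0.36, adjusted p = 0.0040) and mural markers (2 of 11 fell, median -0.16, adjusted p = 0.033). These medians stood beside library 965, whose respiratory chain score lay far above those of the other Tg saline males, and the median of that list was -0.04 without it (adjusted p = 0.0094). With the block for library-number clusters the fibroblast, respiratory chain, macrophage and MHC class II calls ended, and without scaling beyond library size the glucose-use call ended.

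Ang II changed 1038 genes in Tg, 568 higher and 470 lower, of which 84 changed at least 1.5-fold (35 higher, 49 lower). Without libraries 329 and 847 the count was 916, of which 859 were shared, without library 715 (replicate 5 of the Tg Ang II males) it was 656, and with the block for library-number clusters it was 598. The call of Col1a1 ended without any 1 of 5 libraries, with adjusted p from 0.050 to 0.092 (Tg saline female replicates 3 and 5, Tg saline male replicate 5, Tg Ang II female replicate 3 and library 715). The GO term Z disc held 24 of the genes that rose (5.67 by chance, adjusted p = 3.8e-06). The classical complement pathway held 6 that fell (0.525 by chance, adjusted p = 0.016), and KEGG glutathione metabolism held 9 (1.78 by chance, adjusted p = 0.0052).

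**Figure D2:**
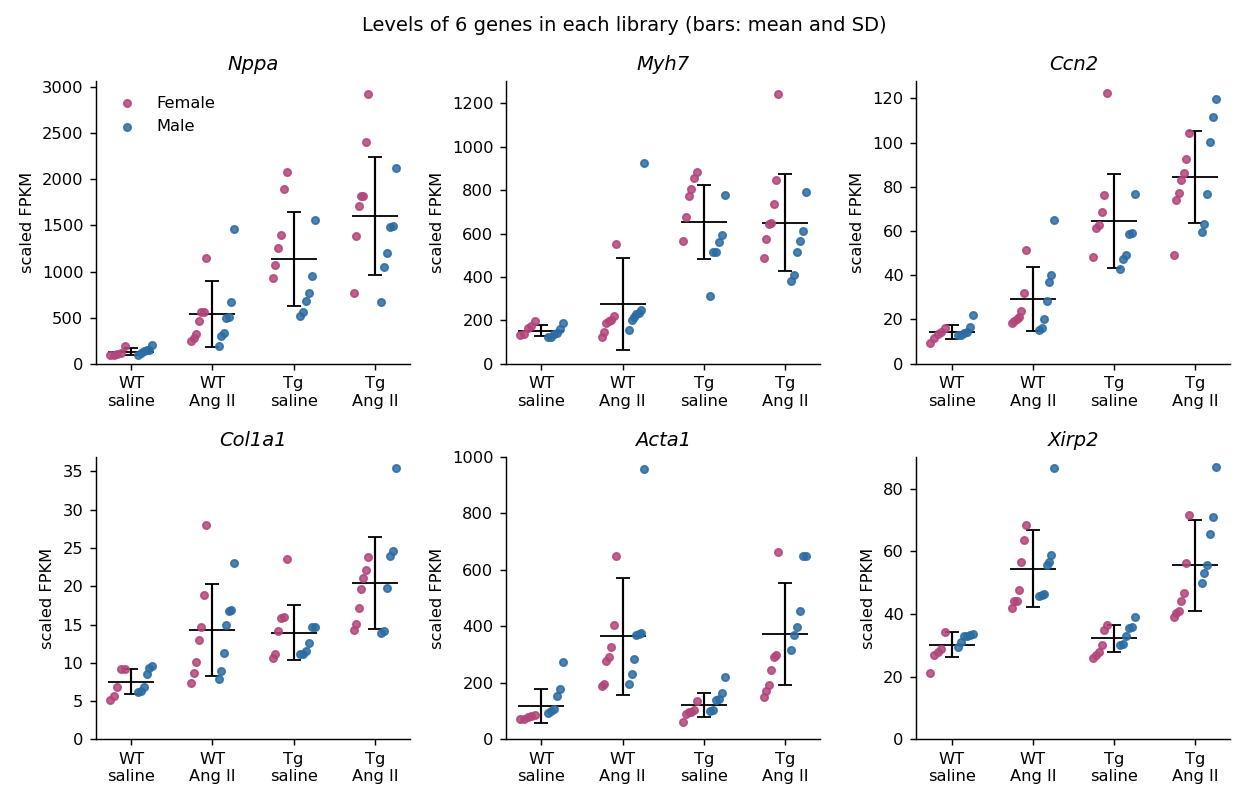
Scaled FPKM of 6 genes in each library by labelled genotype and treatment, coloured by sex, with bars for mean and SD. Acta1 averaged 118 in WT saline, 365 in WT Ang II, 121 in Tg saline and 373 in Tg Ang II, whereas Nppa averaged 132, 537, 1139 and 1603.

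The difference between the Ang II responses of the genotypes was tested gene by gene, which addresses whether LARP6 alters the response. Fbln1, a matrix glycoprotein of basement membranes and elastic fibres, went from 13.4 ± 1.45 to 14.8 ± 2.43 scaled FPKM in WT and from 21.7 ± 3.99 to 16.2 ± 3.58 in Tg (difference of log2 fold changes -0.60 ± 0.09 SE, adjusted p = 8.3e-04). Mybpc2, fast skeletal myosin-binding protein C, went from 3.85 to 7.13 in WT and from 10.3 to 10.2 in Tg (-0.95 ± 0.17, adjusted p = 0.011). Mfap4 gave -1.37 ± 0.29 (adjusted p = 0.050), with 3.84 ± 0.740 and 14.5 ± 8.82 in WT and 16.2 ± 4.14 and 23.4 ± 5.63 in Tg. Tmem30a, a subunit of lipid flippases, gave 0.18 ± 0.04 (adjusted p = 0.040). Sardh, sarcosine dehydrogenase, which was named after its values were seen, gave -0.61 ± 0.13 (adjusted p = 0.050). These were the 5 genes called, 1 higher and 4 lower, and 1136 genes had an unadjusted p under 0.05.

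Of the genes named in every comparison, Nppa came nearest to a call (-1.54 ± 0.35, adjusted p = 0.071), and Col1a1 gave -0.37 ± 0.24 (adjusted p = 0.62), Col1a2 -0.32 ± 0.20 (adjusted p = 0.61) and Col3a1 -0.30 ± 0.33 (adjusted p = 0.79). These are differences of log2 fold changes, and Nppa was already higher in Tg under saline (log2 fold change 3.07). A lower fold change in Tg is thus not by itself a smaller rise in scaled FPKM. The 3 atrial markers, Nppa, Dkk3 (-0.99) and Stard10 (-0.14), of which 0 were called, were the one list that held with an estimated correlation (median -0.99, adjusted p = 0.0012, and adjusted p = 0.021 with an estimated correlation). These are 3 of 7 members, since Myl7, Myl4, Sln and Bmp10 were too low to be tested, and Nppa is also a load marker. Dkk3 and Stard10 were named after their values were seen. Other lists placed lower in Tg by camera, with adjusted p = 0.40 to 0.77 with an estimated correlation, included hypertrophy and load markers (median -0.26, adjusted p = 0.0010), other matrix genes (-0.36, adjusted p = 5.5e-07), myofibroblast markers (-0.57, adjusted p = 0.0062) and resident fibroblast markers (-0.26, adjusted p = 3.7e-05). Macrophage markers (-0.47, adjusted p = 4.4e-04), MHC class II genes (-0.64, adjusted p = 5.0e-06), TGF-beta genes (-0.12, adjusted p = 0.033) and respiratory chain subunits (-0.14, adjusted p = 0.0071) were the rest of that set. The respiratory chain call ended without library 965 (-0.03, adjusted p = 0.34) and without libraries 329 and 847 (-0.10, adjusted p = 0.10). Genes of fatty acid use (0.14, adjusted p = 1.6e-06) and immediate early genes (0.23, adjusted p = 0.0075) were placed higher, with adjusted p = 0.55 and 0.69 with an estimated correlation. Mitochondrially encoded genes were also placed higher (0.10, adjusted p = 0.020, and adjusted p = 0.73 with an estimated correlation), a call that ended with the block for library-number clusters. Their median was 0.06 without scaling beyond library size and 0.02 under quantile normalization. With that block camera at the preset correlation called 6 lists for the difference, so other calls given here ended as well. Adjusted over the list alone, 8 of 15 macrophage markers and 4 of 6 MHC class II genes differed, all with a lower response in Tg.

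DESeq2 called 40 genes for this difference, voom and limma-trend 3 each, and edgeR without libraries 329 and 847 called 3, all shared. With the block for library-number clusters 0 were called by edgeR, and leaving out single libraries gave between 2 and 21, of which Fbln1 and Mybpc2 were called each time.

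**Figure D3:**
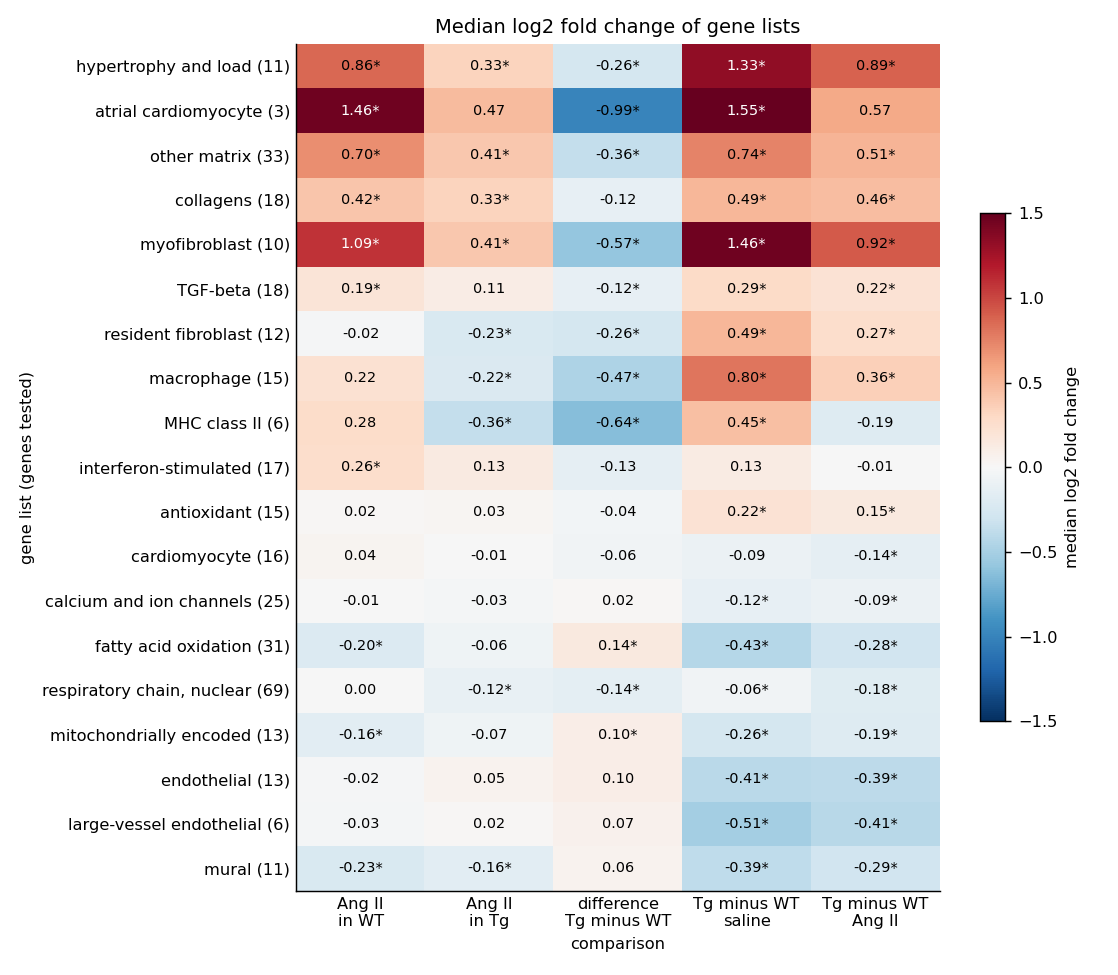
Median log2 fold change of each gene list (rows, with the number of genes tested) in the 4 comparisons of treatment and genotype and in the difference between Ang II responses (columns). An asterisk stands for a camera adjusted p under 0.05 at the preset correlation, and the hypertrophy list has medians of 0.86 with Ang II in WT and 0.33 in Tg.

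Across the 11628 genes, which are not independent replicates, the Ang II log2 fold changes of the genotypes had a Pearson r of 0.452 and a Spearman rho of 0.511, with no library shared between them. Of 569 genes called in both, 568 changed in the same direction, 303 up (55.1 by chance) and 265 down (41.7 by chance). Of the 2160 genes called in WT, 1991 had the same sign in Tg, and the slope of the Tg on the WT fold change over them was 0.461. Over the 1038 genes called in Tg the slope of the WT on the Tg fold change was 0.596, so each set had smaller changes in the genotype that did not choose it. The Pearson r was 0.411 without libraries 329 and 847, and 490 of 491 genes called in both changed in the same direction.

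**Figure D4:**
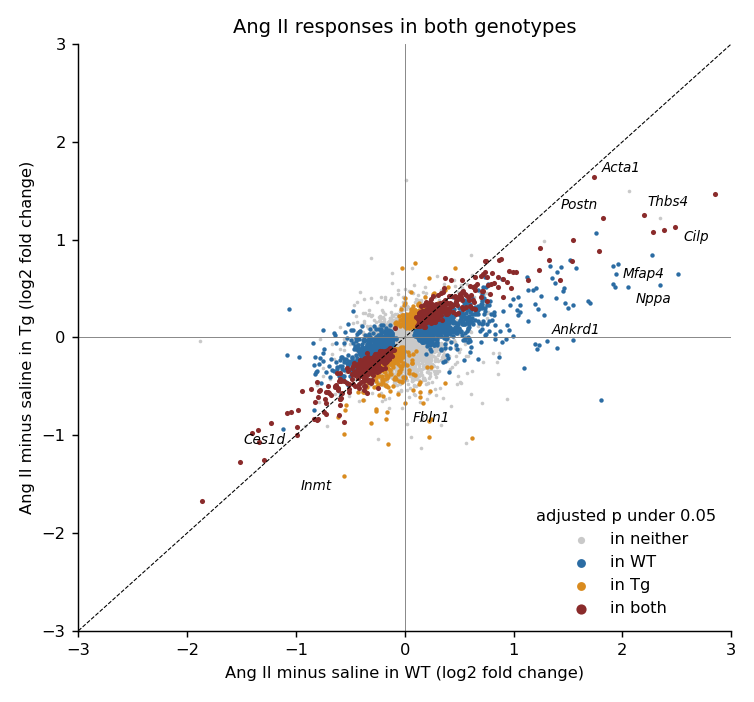
Log2 fold change with Ang II in WT (x axis) and in Tg (y axis) for each gene tested, coloured by the comparisons that called it. The axes end at 3, beyond which 3 genes lie, and 568 of the 569 genes called in both changed in the same direction.

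Under Ang II, Tg hearts still had higher load markers than WT hearts, which addresses how the genotypes differ once treated. Nppa was at 1603 ± 638 scaled FPKM in Tg and 537 ± 357 in WT (log2 fold change 1.54 ± 0.24 SE, adjusted p = 2.6e-06), and Myh7 was at 651 ± 225 and 274 ± 213 (1.23 ± 0.20, adjusted p = 7.3e-06). These WT means keep library 329. Its log2(scaled FPKM + 1) of Myh7 was 9.85, against 7.28 to 7.97 in the other WT Ang II males. Ccn2 was higher by 1.53 ± 0.18, Postn by 1.12 ± 0.23 and Nppb by 0.95 ± 0.28, and Acta1 gave 0.01 ± 0.21 (adjusted p = 0.97). Col1a1 (0.51 ± 0.17), Col1a2 (0.50 ± 0.14) and Col3a1 (0.62 ± 0.22) were higher in Tg (adjusted p = 0.014, 0.0038 and 0.029). Larp6 (3.62 ± 0.40), Rprm (3.45 ± 0.34), Sprr1a (2.78 ± 0.34), Nmrk2 (2.07 ± 0.26), Lgals3 (1.49 ± 0.23) and Serpina3n, a protease inhibitor of the acute phase (1.46 ± 0.25), were among the largest rises. Without libraries 329 and 847 Larp6 stood at 4.62 ± 0.25, Rprm at 4.31 ± 0.20, Sprr1a at 3.30 ± 0.30, Nmrk2 at 2.55 ± 0.19 and Serpina3n at 1.88 ± 0.19. Tgfb2 (1.37 ± 0.16) and Timp1, an inhibitor of matrix proteases (1.34 ± 0.23), were the others. The largest falls were in Strit1 (-1.88 ± 0.31), Scn4b (-1.76 ± 0.19), Mylk4 (-1.44 ± 0.16), Ces1d (-1.30 ± 0.22), Rpl3l (-1.18 ± 0.13), Mir208b (-1.18 ± 0.13), Lgals4 (-1.09 ± 0.17), Cebpb (-1.05 ± 0.39), Slc26a10 (-0.99 ± 0.14) and Arrdc2 (-0.95 ± 0.28).

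Of 18 collagens 13 were higher and 0 lower in Tg under Ang II (15 and 0 adjusted over the list alone, list adjusted p = 6.5e-06), and of 33 other matrix genes 20 were higher and 2 lower (23 and 3 adjusted over the list alone, adjusted p = 2.6e-09). Both lost their call with an estimated correlation (adjusted p = 0.38 and adjusted p = 0.32). Of 11 hypertrophy and load markers 9 were higher, of 10 myofibroblast markers 7, and of 18 TGF-beta genes 10 were higher and 1 lower, each with adjusted p = 0.28 with an estimated correlation. Of 12 resident fibroblast markers 6 were higher (adjusted p = 5.7e-04, and adjusted p = 0.32 with an estimated correlation), and of 15 macrophage markers 8 (adjusted p = 5.9e-04, and adjusted p = 0.38 with an estimated correlation). Of 14 inflammation genes 7 were higher, among them the chemokines Ccl8 (1.28), Ccl7 (0.95) and Ccl2, and 1 was lower (adjusted p = 0.029, and adjusted p = 0.38 with an estimated correlation). Of 15 NRF2 targets 7 were higher, with adjusted p = 0.38 with an estimated correlation.

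Of 13 endothelial markers 12 were lower in Tg under Ang II, with a median of -0.39, among them Esam (-0.51), and of 6 large-vessel markers 4 were lower, each with adjusted p = 0.28 with an estimated correlation. Of 69 respiratory chain subunits 29 were lower and 0 higher, with a median of -0.18, or -0.10 without scaling beyond library size (adjusted p = 2.1e-09, and adjusted p = 0.40 with an estimated correlation). Of 31 genes of fatty acid use 17 were lower (adjusted p = 1.2e-09, and adjusted p = 0.32 with an estimated correlation). Of 13 mitochondrially encoded genes 7 were lower, with a median of -0.19, or -0.09 without scaling beyond library size (adjusted p = 0.40 with an estimated correlation). Quantile normalization, which sets the most abundant genes alike, put that median at 0, with mt-Nd1 turning from -0.25 to 0.03. Of 16 sarcomere and identity genes 8 were lower, among them Ckm (-0.86) and Myl3 (-0.31), and 2 were higher (adjusted p = 0.014, and adjusted p = 0.38 with an estimated correlation). Of 25 calcium-handling and ion-channel genes 11 were lower, among them Kcnip2 (-0.81) and Atp2a2 (-0.49), and 3 higher, and the median of -0.09 was just above 0 without scaling beyond library size (adjusted p = 0.018, and adjusted p = 0.40 with an estimated correlation). Of 11 mural markers 7 were lower and 2 higher, and of 17 collagen-processing genes 5 were higher (adjusted p = 0.047 each, and adjusted p = 0.40 each with an estimated correlation). The LARP6-partner collagens had an adjusted p of 0.043, and adjusted p = 0.38 with an estimated correlation.

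In all, 3814 genes were called under Ang II, 1905 higher and 1909 lower in Tg, of which 425 differed at least 1.5-fold (253 higher, 172 lower). There were 3870 without libraries 329 and 847, of which 3576 were shared, and the calls of the LARP6-partner collagens and of collagen processing ended. The call of mural markers ended without library 965 (adjusted p = 0.053). Both collagen calls also ended without scaling beyond library size, as did inflammation, and 3372 genes were then higher and 927 lower. The call of Col3a1 ended without any 1 of 6 libraries and that of Col1a1 without library 715 (adjusted p up to 0.092 for Col3a1 and 0.050 for Col1a1). The term collagen-containing extracellular matrix held 81 of the genes that were higher (29.3 by chance, adjusted p = 1.8e-16). Mitochondrial inner membrane held 125 that were lower (57.5 by chance, adjusted p = 1.2e-15).

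Female and male hearts differed in the genes of the sex chromosomes and in few others at 1.5-fold or more. Xist, which silences the second X chromosome of females, was higher in females (log2 fold change 5.05 ± 0.20 SE, n = 25 per sex), as were the X-linked genes Kdm5c (0.72 ± 0.04), Eif2s3x (0.69 ± 0.03) and Ddx3x (0.46 ± 0.03), which escape that silencing. The Y-linked Ddx3y (-5.29 ± 0.21) and Eif2s3y (-5.08 ± 0.21) were lower in females. Mean CPM in the sex with less of each gene was 2.69% of the other sex for Ddx3y, 3.08% for Eif2s3y and 3.01% for Xist. Reads carried between libraries may account for that share, so these fold changes may be lower limits. Acta1 was lower in females (-0.62 ± 0.16, adjusted p = 0.015), as were Efemp1 (-0.78 ± 0.10), Ccn5 (-0.71 ± 0.19), Igsf1 (-0.52 ± 0.08), Cxcl14 (-0.50 ± 0.11) and the mitochondrial tRNAs mt-Td (-0.52 ± 0.10), mt-Tv (-0.50 ± 0.10) and mt-Tk (-0.50 ± 0.11). Adamtsl2 (0.58 ± 0.15), Acta2 (0.43 ± 0.11), Nbl1 (0.35 ± 0.07), Fbln1 (0.33 ± 0.05), Itm2a (0.32 ± 0.07) and Clec3b (0.31 ± 0.09) were higher in females. Nppa (0.20 ± 0.18), Nppb (-0.13 ± 0.20), Myh7 (0.15 ± 0.15), Col1a1 (-0.01 ± 0.12), Col1a2 (-0.08 ± 0.10), Col3a1 (-0.05 ± 0.16), Postn (-0.12 ± 0.17), Ccn2 (-0.06 ± 0.13) and Larp6 (-0.67 ± 0.27) did not pass the test. Signs of Nppb, Col1a1, Col3a1, Ccn2 and Larp6 turned under other settings.

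**Figure D5:**
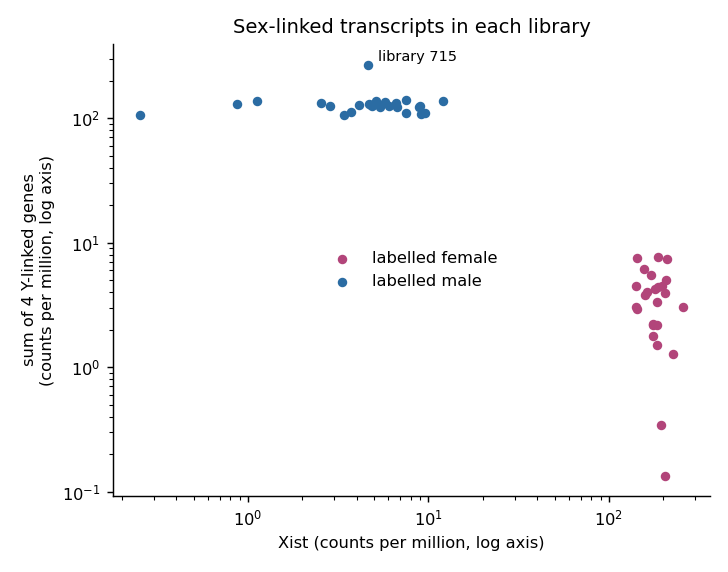
Summed CPM (counts scaled to library size) of 4 Y-linked genes against CPM of Xist in each library (both log axes), coloured by labelled sex. Every labelled male lies at 105 or more on the Y-linked axis and every labelled female at 7.70 or less, with library 715 highest at 269.7.

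All 5 sex-chromosome genes of the list were called (adjusted p = 2.0e-04 with an estimated correlation). In females, camera placed respiratory chain subunits (1 of 69 fell, median -0.11, adjusted p = 2.0e-07), mitochondrially encoded genes (3 of 13 fell, -0.12 and -0.02 under quantile normalization, adjusted p = 5.4e-06), genes of fatty acid use (1 of 31 fell, -0.06, adjusted p = 0.0053), hypertrophy markers (1 of 11 fell, -0.13, adjusted p = 0.047) and red cell transcripts (0 of 5 called, -0.48, adjusted p = 0.0079) lower. It placed endoplasmic reticulum stress genes (2 of 18 rose, 0.07, adjusted p = 0.012), immediate early genes (0 of 13 called, 0.20, adjusted p = 0.026) and collagen processing (2 of 17 rose, 1 fell, 0.06, adjusted p = 0.032) higher. Each of these had an adjusted p of 0.63 to 0.81 with an estimated correlation. Without scaling beyond library size the medians of the lists placed lower were -0.05, -0.07, -0.0039, -0.07 and -0.42, in the order given. Those of the lists placed higher were then 0.12, 0.24 and 0.12.

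In all, 514 genes were called between the sexes, 216 higher and 298 lower in females, and 23 differed at least 1.5-fold (9 higher, 14 lower). Without libraries 329 and 847 there were 444, of which 417 were shared, and with the block for library-number clusters there were 321. Without scaling beyond library size, 1111 genes were higher and 112 lower in females. No GO or KEGG term was enriched (0 of each at an adjusted p under 0.05, Fisher's exact test).

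The response to Ang II was also compared between the sexes. Tfpt, a subunit of a chromatin remodelling complex, was called for a response that differed between the sexes in Tg (0.71 ± 0.14, adjusted p = 0.045), and it was the 1 gene called there by edgeR, with 914 genes at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by voom. Its call ended without libraries 329 and 847 (adjusted p = 0.091). In WT, edgeR called 0 genes for such a difference, with 751 genes at an unadjusted p under 0.05 and 1 gene by DESeq2. For the sex difference in the effect of genotype on the Ang II response edgeR called 0 genes, with 1225 at an unadjusted p under 0.05 and 2 by DESeq2. For a genotype effect that differs between the sexes edgeR called 0, with 414 at an unadjusted p under 0.05 and 2 by DESeq2. Without libraries 329 and 847 edgeR called 0 genes for each of these differences between the sexes. Taken in each sex alone, Ang II called 708 genes in WT females, 826 in WT males, 14 in Tg females and 889 in Tg males. The count in Tg males was 427 without library 965, 290 without library 715 and 77 without both, and in Tg females it was then 16, 15 and 16.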

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

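The tests of the label of library 329 and the shuffled splits were chosen after the results were seen, and the tests of differences between Ang II responses were chosen in advance. Library 329, replicate 5 of the WT Ang II males, stood far from the rest of its group in log2(scaled FPKM + 1) of Larp6 (9.96, others 4.37 to 5.99) and of Myh7 (9.85, others 7.28 to 7.97). It also stood apart in the mean log2 level of the La-related protein list, which holds Larp6 (6.28, others 5.38 to 5.68), and of the mural list (4.98, others 5.51 to 5.71).

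A wrong genotype label on library 329 may account for its Larp6 level. Over 3869 genes that differed between the genotypes under Ang II with both doubtful libraries left out, library 329 lay nearer the Tg mean in 68.5% of genes, each library being set against the means of its own treatment and sex, where other WT libraries gave 12.0% to 54.4% and other Tg libraries 64.3% to 93.2%. An exchange with library 847, which an opposite mismatch of letters would invite, is argued against by the Larp6 level of library 847, which at 1122 scaled FPKM lay far above the 63.4 of the highest other WT library, and by its 82.6% of genes nearer the Tg mean. What stays open is how that label arose, and no biological explanation was tested.

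Library 965, replicate 6 of the Tg saline males, had the lowest FPKM scaling factor of its group (0.775, others 0.955 to 1.05), the highest mean log2 level of respiratory chain subunits (8.11, others 7.17 to 7.42), the lowest of clock genes (3.95, others 4.46 to 4.72) and the highest log2 Nppb (9.39, others 7.38 to 7.72). Library 157, replicate 1 of the WT saline males, had a low log2 Larp6 (2.72, others 4.98 to 6.01), a low La-related protein score (5.25, others 5.52 to 5.63) and a low score of sex-chromosome genes (3.99, others 4.44 to 4.54). The La-related protein list holds Larp6, so its low score is not a separate result. Library 715, replicate 5 of the Tg Ang II males, had the highest hypertrophy score of its group (9.50, others 8.69 to 8.93).

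Scores of single lists, as mean log2 CPM, also set apart the following libraries. Library 239 (WT saline female replicate 1) stood at 3.70 in myofibroblast markers and 6.53 in calcium handling and ion channels, and library 968 (WT saline female replicate 5) at 3.96 in TGF-beta genes. Library 528 (Tg saline male replicate 5) stood at 7.60 in glucose use, and library 326 (Tg Ang II male replicate 3) at 5.43 in immediate early genes and 3.93 in large-vessel endothelial markers. Library 159 (WT Ang II male replicate 1) stood at 3.43 in the cell cycle, against 0.83 to 1.65 in the others, and at 9.90 in log2 Acta1. Library 778 (WT Ang II male replicate 7) stood at 2.74 in interferon-stimulated genes, library 720 (WT Ang II female replicate 4) at 5.99 in mural markers, and library 530 (Tg Ang II male replicate 4) at 3.26 in the adipocyte list. Library 488 (WT saline male replicate 3) stood at 3.44 in red cell transcripts, against 5.55 to 5.84. Library 165 (WT Ang II female replicate 3) stood at 7.77 in red cell transcripts, against 4.27 to 5.45, and at 4.09 in clock genes. Library 154 (Tg Ang II female replicate 1) stood at -1.92 in sex-chromosome genes, and library 779 (WT Ang II female replicate 7) at 9.11 in log2 Myh7. Each is the gap of an extreme library to its nearest neighbour against the group's range, which chance puts past its limit in about 1 of 20 groups. Of 392 combinations of group and quantity 28 stood apart in this way, where chance gives 19.6, and they fell on 16 libraries. Some quantities share genes, such as Larp6 and the La-related protein list, so the combinations are not independent.

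Genes whose Ang II response differed between the genotypes by a test of the difference itself were Fbln1 (-0.60), Sardh (-0.61), Mybpc2 (-0.95), Mfap4 (-1.37) and Tmem30a (0.18), and the atrial list, with 3 of 7 members tested and Nppa among them, had a median of -0.99 (adjusted p = 0.021 with an estimated correlation). When treatment labels were shuffled within genotype and sex, 3 of 100 splits, the real one included, called as many as the 5 genes. That share is small, but the shuffles ignore the clusters of library numbers, and with these as a block 0 genes were called, so chance is not excluded. The highest other split called 152, several times the real count, as a split that follows a structure of the samples can give, but no such structure was tested, and the median of the other splits was 0. Tfpt was called for a response that differed between the sexes in Tg (0.71). When sex labels were shuffled within genotype and treatment, 3 of 100 splits called at least that 1 gene, with 2 genes in the highest other split. That share for 1 gene does not exclude chance either. In addition, 0 genes were called with no filter, no scaling, quantile normalization, quality weights, only the groups compared, voom, and each fit without libraries 329 and 847.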

How the results depend on the processing

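The fits by DESeq2, TMM, voom with median-of-ratios scaling and limma-trend on log2(scaled FPKM + 1), and those without libraries 329 and 847 or without 965, or without 965 and 715 in each sex of Tg, were chosen after the results were seen. The genotype difference of Larp6 kept its call and direction under each alternative run, from 4.20 to 4.85. Over alternatives other than single left-out libraries, 5906 values of single genes kept their direction and side of the threshold, 161 lost the call, 49 gained one and 23 turned sign. Of the main values, 172 kept close to their value (counts within 1.5 times) and 53 moved. Depth limits the lowest 1% of genes most, with a mean count of at most 19.1 and a coefficient of variation from counting of 22.9% or more, against 2.89% for the median gene. In the simulated counts, 85.1% of genes altered 1.5-fold were recovered for Ang II in WT but 25.4% for the 3-way difference.

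Genes called for the genotype by Ang II difference numbered 3 with a pseudocount of 0.1, 2 with no filter, 8 without scaling, 2 with quantile normalization, 14 with quality weights, 2 with the robust fit, 0 with the number block, 40 with DESeq2, 3 with limma-trend, 3 with voom, 3 without libraries 329 and 847, 1 without 965 as well, and 0 without 329 and 847 with the block. The 1 gene for sex by Ang II in Tg became 0 with no filter, no scaling, quantile normalization, quality weights, only the groups compared, voom, and all fits without 329 and 847. DESeq2 called 1 gene for sex by Ang II in WT and 2 each for the other counts of 0. An FPKM minimum of 5, which tests fewer genes, gave 1308 for Ang II in WT, 2582 and 2198 for genotype under saline and Ang II, and 334 for sex. A 1.5-fold minimum, stricter by construction, gave 269, 84, 786, 425 and 23 for Ang II in WT and in Tg, genotype under saline and Ang II, and sex. Sex gave 1223 without scaling. With the block, Ang II in Tg gave 598 and sex 321, and 619 and 292 without 329 and 847. With an estimated correlation the lists called numbered 0 for Ang II in WT and in Tg and for genotype under saline and Ang II, and 1 for the genotype by Ang II difference, and the same without 329 and 847. By fry 1 list was called for Ang II in Tg and 1 for that difference. With the block, camera at the preset correlation called 6 lists for that difference, fewer than without the block. The r between the Ang II responses was 0.576 with a pseudocount of 0.1.

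Signs of single genes that turned were all of values without a call, except for mt-Co3 in Tg under saline (0.0058) and mt-Nd1 in Tg under Ang II (0.027) with quantile normalization. Without scaling these were Myh7 for Ang II in Tg (0.00045) and Col1a1 (0.041) and Col3a1 (0.0080) for sex. With quality weights they were Myh7 for Ang II in Tg (0.0089), Acta1 for the genotype by Ang II difference (0.062) and Ccn2 for sex (0.017). With the block they were Myh7 (0.11), Acta1 (0.16), and mt-Atp8 (-0.0037) and mt-Co1 (-0.0014) for the difference. Without 329 and 847 Ccn2 for sex was 0.0012. Without 965 as well, Myh7 was 0.061, mt-Nd3 for the difference 0.029, and Ccn2 (0.029) and Nppb (0.074) for sex. Without 329 and 847 with the block, C1qc for Ang II in Tg was 0.013, Myh7 0.065, Acta1 0.17, mt-Co1 -0.0035, and Ccn2 (0.013) and Larp6 (0.056) for sex. Medians of called lists turned without scaling for respiratory chain subunits under saline (-0.06 to 0.07) and for calcium handling under saline (-0.12 to 0.02) and under Ang II (-0.09 to 0.0019). The call of mitochondrially encoded genes in the difference ended with the block, where their direction turned.

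Leaving out each of the 50 libraries gave 656 to 1128 genes for Ang II in Tg, 2 to 21 for the genotype by Ang II difference, 0 to 1 for sex by Ang II in Tg and 0 to 1 for the 3-way difference. Single values ranged from -0.10 to 0.052 for Myh7 and -0.15 to 0.027 for Larp6 with Ang II in Tg, -0.28 to 0.088 for Acta1 and -0.29 to 0.012 for mt-Nd3 in the difference, and -0.16 to 0.21 for Acta1 in Tg under Ang II. For sex they ranged from -0.076 to 0.034 for Col1a1, -0.12 to 0.011 for Ccn2 and -0.14 to 0.013 for Col3a1. Where no construction is named, the cause was not tested.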

Other observations

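The tests of sex-linked reads, shared genes and other splits of the samples were chosen after the results were seen, and the gene lists in the next paragraphs were tested as planned. Genes of the cell cycle were not called as a list, yet with Ang II in WT 5 of 11 rose, among them Mki67 (1.33 ± 0.37), Ccna2 (1.57 ± 0.38) and Top2a (1.43), and Cenpf fell by 1.23 (list adjusted p = 0.28). Mean log2 CPM of the list was 3.43, 3.17 and 2.54 in libraries 159, 779 and 165 of the WT Ang II group, and 0.83 to 1.65 in its other libraries, against 0.82 to 1.70 in WT saline. Under saline in Tg 3 of these genes were higher and 1 lower. The renin-angiotensin and natriuretic list was not called in any comparison, but Ace, the converting enzyme, was higher in Tg under saline (9.01 to 15.4 scaled FPKM, 0.78 ± 0.11) and Agtr1a, the main Ang II receptor, was lower (10.6 to 6.77, -0.64 ± 0.10). With Ang II in WT Ace rose by 0.33, Ednrb rose by 0.52 and Agtr1a fell by 0.37. Of 18 endoplasmic reticulum stress genes Chac1 and Atf4 rose with Ang II in WT (0.91 and 0.21), 0 of 18 changed in Tg, and Herpud1 (-0.56), Dnajb9 (-0.29) and Hspa5 (-0.18) were lower in Tg under saline.

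Of 19 genes of glucose use 3 rose and 3 fell with Ang II in WT, and 3 were higher and 6 lower in Tg under saline, among them Ldhb (-0.59) and Eno3 (-0.76). Of 13 immediate early genes Myc was higher (1.13 ± 0.15) and 4 were lower in Tg under saline, among them Zfp36 (-0.73) and Dusp1 (-0.66). Of 7 La-related protein genes Larp6 and Larp1 (0.18) were higher and Larp1b (-0.27) lower in Tg under saline. Of 15 clock genes 0 changed with Ang II in WT or Tg by edgeR, with list adjusted p = 0.70 and 0.96. Red cell transcripts gave 0 of 5 called in every comparison of treatment and genotype. Of 14 inflammation genes 5 were higher and 2 lower in Tg under saline, among them Serpina3n (1.70) and Ccl8 (1.66) and, lower, Cxcl12 (-0.73). Lists with too few members for a set test gave Pparg of the adipocyte list at 0.07 with Ang II in WT and -0.27 in Tg under saline, Cidea of the brown adipocyte list at 0.20 with Ang II in WT, Krt18 of the mesothelial list at 1.75 in Tg under saline, and Cdh19 of the nerve and Schwann cell list at -0.58 with Ang II in WT. Of the B and plasma cell list Ighm and Igkc were tested and 0 called, and of 13 T cell markers 0 were expressed enough to be tested.

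The effect of the transgene under saline and the effect of Ang II in WT moved many of the same genes. Across genes they had r = 0.695, with 731 genes called higher in both, 614 lower in both and 63 in opposite directions, but both use the same WT saline libraries, and 20 simulations of no change with shared controls gave r = 0.534 on average, at most 0.652, and 0 genes called in both. With those libraries split between the comparisons in 20 ways, 363 genes were called higher and 264 lower in both on average (106 and 89.2 if independent), and the lowest r was 0.512, and 0.465 without libraries 329 and 847, which argues against shared controls and against library 329 as the whole cause. Under saline the endothelial markers had a median of -0.41 and the fibroblast markers 0.49. This argues only against a lower share of cardiomyocytes in Tg samples with the other cell types in fixed proportion. A lower share with other cell types shifting separately could not be decided. Also open, and not tested, is whether overexpressed LARP6 raises part of the program that Ang II raises. Acta1 and Xirp2 rose with Ang II in both genotypes and not with the transgene. A first form of the test of shared controls, which set split against simulated values that keep the sharing, was replaced once its value was seen.

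Reads of the wrong sex were present in every female library. The 4 Y-linked genes summed to 0.135 to 7.70 CPM in the 25 females, against a median of 126 in males, and Xist in males ranged from 0.253 to 12.1 against a median of 184 in females. Reads of X-linked homologues are argued against by the ratio of Y genes to those homologues, which varied 64.0-fold over the females. That width rests on libraries 154 (Y-linked genes at 0.135 CPM) and 153 (0.340). The other females ranged from 1.28 to 7.70, still wider than the homologues, at 322 to 469 in all females. Reads carried between libraries may account for it, since mean ratios to the other sex lay close together at 2.69% for Ddx3y, 2.52% for Uty, 2.95% for Kdm5d, 3.08% for Eif2s3y and 3.01% for Xist, the highest 1.23 times the lowest. Larp6 in WT libraries other than 329 stood at 3.39% of the Tg mean, so how much of it is the mouse's own Larp6 cannot be told apart from carried reads. Rprm stood at 3.83% in the same libraries.

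Among 4 relations of that kind, Y-linked reads and Larp6 in WT females gave r = 0.856 (permutation p = 7.8e-04, adjusted p = 0.0016) and rho = 0.755 (permutation p = 0.0064, adjusted p = 0.013, n = 12), and r = 0.57 without the 2 farthest libraries. Xist and Larp6 in WT males other than 329 gave r = -0.0966 (permutation p = 0.77) and rho = -0.189 (permutation p = 0.56, n = 12), and r = -0.598 without the 2 farthest libraries. Rprm and Larp6 gave r = 0.905 (permutation p = 1e-05, the smallest possible, adjusted p = 4e-05) and rho = 0.863 in WT other than 329 (n = 24), and 0.851 without the 2 farthest. In Tg they gave r = 0.470 (permutation p = 0.018, adjusted p = 0.024) and rho = 0.440 (permutation p = 0.028, adjusted p = 0.037, n = 25), and 0.517 without the 2 farthest. Library 715 had 269.7 CPM of Y-linked genes where other males had 105 to 139.6, which was 2.06 to 2.23 times the mean of the 24 other males in each of the 4 genes.

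Labels were also shuffled within the other factors, 100 splits in each case with the real one included. For Ang II in WT 1 split, the real one, gave 2160 genes, and the highest other gave 51. For Ang II in Tg 1 split reached 1038, and the highest other gave 1. For genotype under saline 1 split reached 4720 (highest other 569), under Ang II 1 split reached 3814 (highest other 3), and for sex 1 split reached 514 (highest other 3). A free shuffle of the labels can be excluded as the source of these 5 counts, but the shuffles ignore the clusters of library numbers. With the clusters as a block edgeR called 2008, 598, 3970, 3600 and 321 genes, in the order above, and those fits were not shuffled. The counts of 0 are reached by all 100 splits whatever the data, so the shuffles decide nothing there. Their highest other values were 10 for sex and Ang II in WT, 20 for sex and genotype, and 421 for the 3-way difference, with a median of 0 in each. A split that follows a structure of the samples can give such single high counts, but no such structure was tested.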
